A study of Homo sapiens with 2 samples.

How the data were processed

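The series holds 2 chromatin immunoprecipitation sequencing libraries from MCF-7, an established human breast cancer cell line of the oestrogen receptor positive, luminal type. One library was made with an antibody against STAT1, a transcription factor activated by interferons, and is called the STAT1 library here. The other is labelled as the IgG control and is called the control library. The protocol shared by both libraries names stimulation of CD95 (Fas, a death receptor) with an anti-APO-1 antibody or IgG at 100 ng/ml together with protein A at 1 ng/ml. The labels give IgG as the antibody of the control library, while the protocol also names IgG as a stimulus, so it stays open whether IgG replaced the STAT1 antibody, the stimulus or both. There is 1 library per group and no replicate.

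BWA 0.6.1, HOMER 4.1 and the genome build hg19 are named in the submitters' processing notes, with no role given there. Per the file headers, peaks were called with HOMER findPeaks in its transcription factor style, separately in each library and without a control library as background. Per the file headers, a peak needed at least 7 tags in the STAT1 library and 14 in the control library (a false discovery rate of 0.1%), at least 4.0-fold more tags than the surrounding 10.0 kb, and a Poisson p-value of 0.0001 or less against that region. At most 1.0 tag per base position was considered, and peaks with over 2.0 times fewer tag positions than their tag number predicts were removed. The file headers give a peak size of 151 bp in the STAT1 library and 156 bp in the control library, without saying how it was set.

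Each peak carries values made by the authors. The deposited normalized tag count is a signal, the tags in the peak scaled to 10000000 total tags, and it is called peak height here. The deposited findPeaks score is a whole number that starts at the tag threshold of each library, and it is read here as a tag number limited to 1 tag per base position. It is not strictly a number of positions inside the peak, since 1 STAT1 peak and 4 control peaks score above the positions that their width holds on both strands. The deposited fold is the ratio of the peak's tag density to that of the surrounding region, and the deposited clonal fold is the ratio of expected to observed tag positions. The focus ratio is a fraction per peak, per the file headers, and the p-value against the local region is also the authors'. The last 2 were not used in comparisons. All scores and folds describe peaks within their own list. Peak height, scaled to the same total in both libraries, is the main measure compared between lists, and folds and scores set side by side are each library's own values.

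From these files, peaks of the 2 lists were called shared where they had at least 1 bp in common, computed in Python in place of the bedtools named in the plan. The other peaks are called STAT1-only or control-only, which means that the other list has no overlapping peak, not that the other library has no tags there. The number shared was set beside 1000 random placements of the control peaks on their own chromosomes, over the span from the first base to the last peak. Shares carry exact (Clopper-Pearson) 95% binomial intervals and medians carry 95% order-statistic intervals. These intervals cover counting error only, treat neighbouring peaks as independent, and say nothing of variation between experiments. No test between the conditions was possible. Tags without molecular identifiers are not independent molecules. The tags in a peak were obtained from its height and the library total, and the local background of a peak is its height divided by its fold over the surrounding region. Medians of this background per 5 Mb did not fall below about 0.75 in the STAT1 library and 0.77 in the control library. Many lay close to these values, so the background appears to have a floor and is not a measured local value everywhere. Peaks were also counted in 5 Mb windows. A window with a peak of height 100 or more in either library is called a tall-peak window, and one with at least 20 STAT1-only peaks is called crowded. These bounds, the distance of 100 kb from a tall shared peak and the same window rule on control-only peaks were chosen after the data were seen.

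The peaks named singly follow a rule fixed before the data were examined, namely the 20 STAT1-only, 10 control-only and 10 shared peaks with the highest score. Other peaks are named as chosen after their values were seen. Comparisons by gene, distance to transcription start sites, annotation class and STAT motif were planned, with 11 gene lists. They were not run, because no hg19 sequence or annotation was used here and the gene table at hand follows another build. Peak positions are therefore given without gene names, 1-based and as the files give them. The overlap count was tested on 6846 simulated peaks with 200 planted shared peaks, of which 200 were found with 0 false ones. The alternatives were other overlap rules, stricter thresholds, lists of equal length, other random placements and the removal of unplaced sequences. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.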

Results

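STAT1 occupancy after CD95 stimulation was profiled in MCF-7 cells by chromatin immunoprecipitation sequencing, with an IgG library as control. The STAT1 library held 16201476 tags and the control library 38147481. By the tag density in the file headers, 4372000 tags of the STAT1 library (26.99%) and 33258000 of the control library (87.2%) remained when 1 tag per base position was counted. Peaks held 1.09% of the tags in the STAT1 library and 0.849% in the control library. With 1 library per group, each value below describes these libraries, and no difference has a replicate check.

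The first question was how many sites each library marked and how strong they were. The STAT1 library had 2767 peaks and the control library 4079. The order turned at 1.5 times the local fold, where 2050 and 1613 remained. A peak at the tag threshold has 7 tags against 0.33 expected in the STAT1 library, and 14 against 2.59 in the control library. The fold bound therefore falls more on weak control peaks, so the turn follows at least in part from depth and threshold. The STAT1 peaks had a median height of 19.1 tags per 10000000 (interquartile range 13 to 27.8), and the control peaks 5.2 (4.5 to 9.7). Heights count repeated tags, 3.71 per distinct position in the STAT1 library and 1.15 in the control library. Each list also starts at its own tag threshold. The 2 medians therefore depend on depth, repeated tags and threshold, and do not compare the strength of binding. The peak score, a tag number limited by position and not scaled to depth, had a median of 8 in the STAT1 list and 18 in the control list. Of the STAT1 peaks, 1450 (52.4%) lay at the tag threshold of 7 or 1 above it, and 569 (20.6%) reached the threshold of 14 used for the control library. Local filtering had removed 58.7% of the 6705 putative STAT1 peaks and 83.7% of the 25823 putative control peaks.

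The control library shows which regions gather tags without the STAT1 antibody, as its antibody label reads. Of the STAT1 peaks, 975 (35.2%, 95% interval 33.5 to 37.0) overlapped a control peak, which was 23.9% (22.6 to 25.2) of the control list. Random placement of the control peaks gave 6.24 ± 2.38 shared peaks (mean and SD of 1000 placements), so the observed number was 156 times higher. The strongest STAT1 peaks were the ones most often shared. Of the 964 STAT1 peaks with a score of 7, 14.4% (12.3 to 16.8) were shared, against 48.7% (44.1 to 53.3) of the 474 with scores of 10 to 13 and 79.3% (73.3 to 84.4) of the 222 with scores of 28 or more. The control list showed the same order, from 3.26% (2.35 to 4.40) of its 1258 peaks with scores of 14 or 15 to 87.6% (84.5 to 90.3) of its 541 peaks with scores of 56 or more. Among the 569 STAT1 peaks at or above the control threshold, a setting added after the data were seen, 70.1% were shared.

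**Figure D1:**
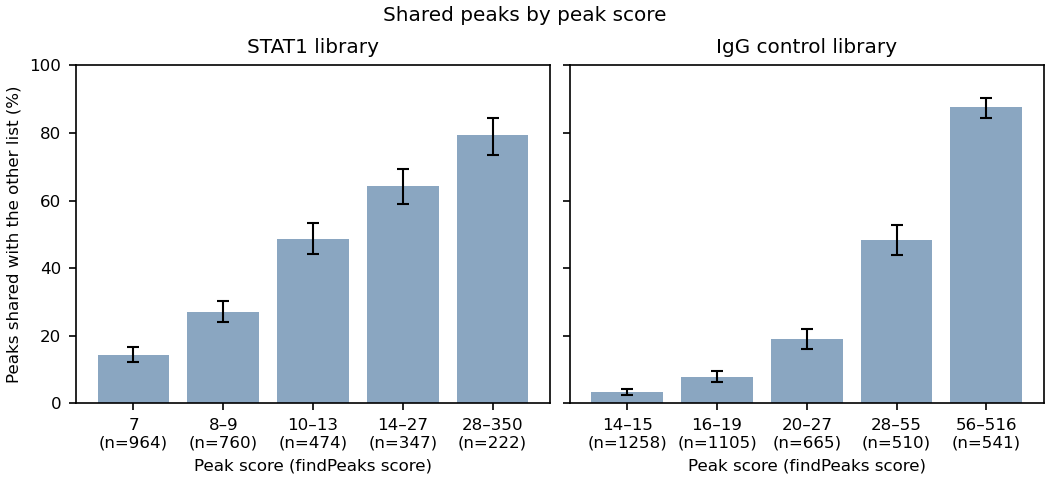
Percentage of peaks that overlap a peak of the other list (y axis), by the authors' findPeaks score (x axis), for the STAT1 library (left) and the IgG control library (right). Bars are percentages, error bars exact 95% binomial intervals and n the peaks per score range. The share rose from 14.4% to 79.3% in the STAT1 list and from 3.26% to 87.6% in the control list.

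The tallest shared peaks had nearly equal heights in both libraries. The highest shared peak lay on chromosome 1 at 121485134 to 121485284, with a height of 10071.9 in the STAT1 library and 10593.1 in the control library. The second, on chromosome 19 at 27732056 to 27732206, had heights of 2721.4 and 2753.8. Of the 10 shared peaks with the highest score, 4 others lay on chromosome 10 between 42385493 and 42599759, with STAT1 heights of 799.3 to 1377.0 and control heights of 944.5 to 1622.6. These places flank centromeres in hg19, where satellite repeats are incompletely assembled. Over the 82 shared peaks of height 100 or more in both libraries, the median ratio of STAT1 to control height was 0.998 (95% interval 0.956 to 1.03), and none differed by more than 2-fold. Requiring this height in both libraries favours similar heights. Over all 314 shared pairs in tall-peak windows the median ratio was 1.02 (0.994 to 1.06), with 24 pairs over 2 times and 4 under 0.5 times.

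Sharp peaks at single places were shared as well. In 46 shared pairs the peak stood at least 50-fold over its surroundings in both libraries, and their median height ratio was 1.08 (interquartile range 0.926 to 1.25). Requiring the bound in both libraries favours pairs of similar height. At the same bound there were 16 STAT1-only and 0 control-only peaks, the highest control-only fold being 40.57. Folds depend on the depth of each library. This bound, and the following examples, were chosen after the values were seen. On chromosome 3 at 196625652 to 196625802 the fold over the surroundings was 143.12 in the STAT1 library and 155.77 in the control library. On chromosome 5 at 177026980 to 177027130 it was 143.56 and 126.67. On chromosome 11 at 118306998 to 118307148 it was 105.96 and 143.98, with heights of 688.8 and 1253.0.

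Over all 975 shared pairs, the median height ratio was 1.12 (95% interval 1.09 to 1.16; interquartile range 0.880 to 1.55). Heights rose together across pairs (Spearman rho 0.830; peaks are not independent replicates). In 143 pairs (14.7%) the STAT1 height was over 2 times the control height, and in 14 (1.44%) it was under 0.5 times it. The 143 pairs had a median score of 8 in the STAT1 library and 20 in the control library, and 91 of them had a STAT1 score of 9 or less. The largest ratio, 7.53, was on chromosome 14 at 55369268 to 55369418, with heights of 33.9 and 4.5 and a score of 11 in the STAT1 library. By score relative to the library's distinct tags, the median ratio was 2.30, with 567 pairs (58.2%) over 2 times and 0 under 0.5 times. The thresholds of 7 and 14, set against 4372000 and 33258000 distinct tags, raise this ratio for pairs near them. This covers part of the pairs, as 27.1% of the shared STAT1 peaks and 4.21% of the shared control peaks lay at their threshold or 1 above it. The limit of 1 tag per base position also holds down the scores of tall peaks in both libraries. The tallest pair had scores of 350 and 516 at heights of 10071.9 and 10593.1. The ratio by score is therefore not a measure of STAT1 enrichment at shared peaks.

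**Figure D2:**
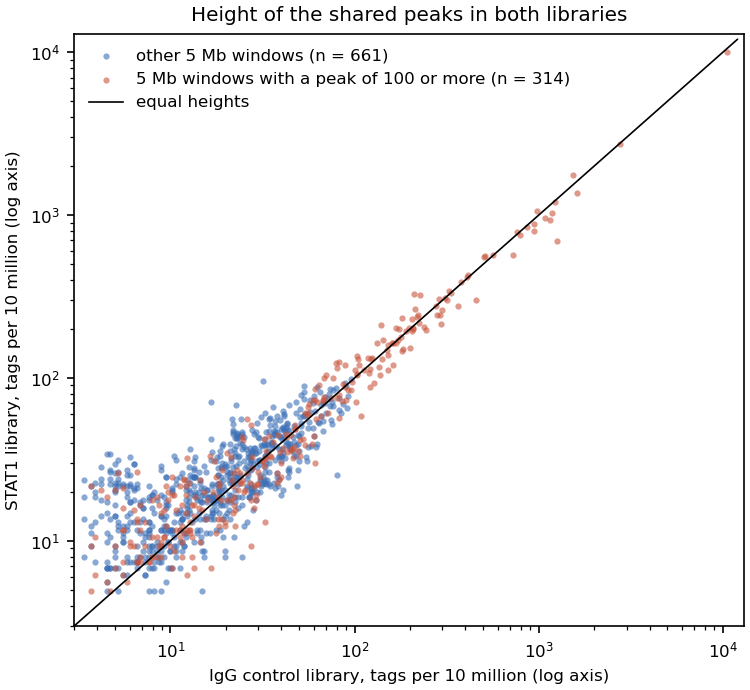
Height of each shared peak, as tags per 10000000, in the IgG control library (x axis, log) and the STAT1 library (y axis, log). Points are 314 pairs in 5 Mb windows with a peak of height 100 or more and 661 pairs elsewhere, and the line marks equal heights. Tall pairs follow the line (median ratio 0.998 where both heights reach 100), and for the pairs elsewhere the interquartile range of the ratio was 0.895 to 1.71.

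The peaks found only in the STAT1 list, beside shared peaks of unequal height, are sites at which the STAT1 pull-down could differ from its control. There were 1792 STAT1-only peaks (64.8%, 95% interval 63.0 to 66.5), with a median height of 17.9 and a median score of 8. Of these, 1186 (66.2%) lay at the threshold of 7 or 1 above it. They stood a median of 7.79-fold over their surroundings (interquartile range 5.25 to 13.2). The 3104 control-only peaks, in their own library, stood at 5.04-fold (4.49 to 6.05). Among the STAT1-only peaks, 11.9% had a control peak within 1 kb of their centre and 26.5% within 10 kb.

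Most of the strongest STAT1-only peaks lay near tall shared peaks. Of the 20 with the highest score, 17 had a shared peak of height 100 or more in both libraries within 100 kb, against 92 (5.13%, 95% interval 4.16 to 6.26) of all STAT1-only peaks. This distance was chosen after the data were seen. Of the 20, 16 stood less than 7-fold over their surroundings. The first was on chromosome 10 at 42385148 to 42385298, with a score of 201, a height of 1356.7 and a 6.66-fold excess over its surroundings. A shared peak with a height of 938.2 starts close by, at 42385493. The third was on chromosome 1 at 121484034 to 121484184, with a height of 2506.6 and a 5.0-fold excess. The 3 without a tall shared peak nearby lay on chromosome 5 at 11112 to 11262, on chromosome 1 at 569358 to 569508 and on chromosome X at 61839238 to 61839388. The last had a score of 46, a height of 232.7 and a 156.62-fold excess. Its window, chromosome X from 60 to 65 Mb, held 30 control peaks, 12 of them shared. Without repeat annotation, distance from a tall shared peak does not place these 3 peaks outside repeat sequence. The control-only peak with the highest score lay near the end of chromosome 5, at 10676 to 10832, and another of its 10 highest-scoring peaks lay at 11337 to 11493, with the STAT1-only peak of that chromosome between them. Of these 10, 7 lay within 100 kb of a tall shared peak, against 66 (2.13%, 1.65 to 2.70) of all control-only peaks. Outside tall-peak windows, 87 STAT1-only peaks reached the control threshold of 14.

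STAT1-only peaks were unevenly spread over the chromosomes. Chromosomes 17 and 20 held 377 of them (21.0%, 95% interval 19.2 to 23) but 268 of the control-only peaks (8.63%, 7.67 to 9.68), a 2.44-fold difference in share (2.08 to 2.86). MCF-7 is known to carry extra copies of parts of both chromosomes. Chromosome 1 held 15.5% and 8.09% (ratio 1.91, 1.61 to 2.28), and chromosome 8 held 5.97% and 3.99% (ratio 1.49, 1.14 to 1.95). On chromosome 3 the shares were 8.87% and 6.38% (ratio 1.39, 1.12 to 1.72). Among chromosomes 1 to 22 and X, the lowest ratios were those of chromosomes 12 and 14, 0.458 (0.300 to 0.681) and 0.470 (0.329 to 0.660). Much of the excess on chromosomes 17, 20 and 3 lay in a few windows. Of 179 STAT1-only peaks on chromosome 17, 124 lay from 55 to 60 Mb. Of 198 on chromosome 20, 64 lay from 45 to 50 Mb and 83 from 50 to 55 Mb. Of 159 on chromosome 3, 92 lay from 60 to 65 Mb. In that order, these windows held 7, 29, 9 and 1 control-only peaks. Their ratios therefore do not describe whole chromosomes.

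The same gathering of STAT1-only peaks in a few regions was counted over the whole genome. The 15 crowded windows of 5 Mb held 694 of them (38.7%, 36.5 to 41.0) and 203 of the control-only peaks (6.54%, 5.70 to 7.47). They were chosen by their number of STAT1-only peaks, so the higher share of these follows from the choice. Chosen in the same way by control-only peaks, a rule added after the data were seen, 28 windows held 780 control-only (25.1%) and 413 STAT1-only peaks (23.05%), with at most 56 control-only peaks in a window, and 5 windows met both rules. The fullest window by STAT1-only peaks, chromosome 17 from 55 to 60 Mb, held 124 STAT1-only and 7 control-only peaks, the former between 56660112 and 59940996. Chromosome 3 from 60 to 65 Mb held 92 and 1. Chromosome 20 held 64 and 29 from 45 to 50 Mb, and 83 and 9 from 50 to 55 Mb. On chromosome 1, the window from 145 to 150 Mb held 66 and 27. In 12 of the crowded windows, which had no tall peak, the 627 STAT1-only peaks stood a median of 5.47-fold over their surroundings, against 11.2-fold for the 862 STAT1-only peaks in the other windows without tall peaks.

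**Figure D3:**
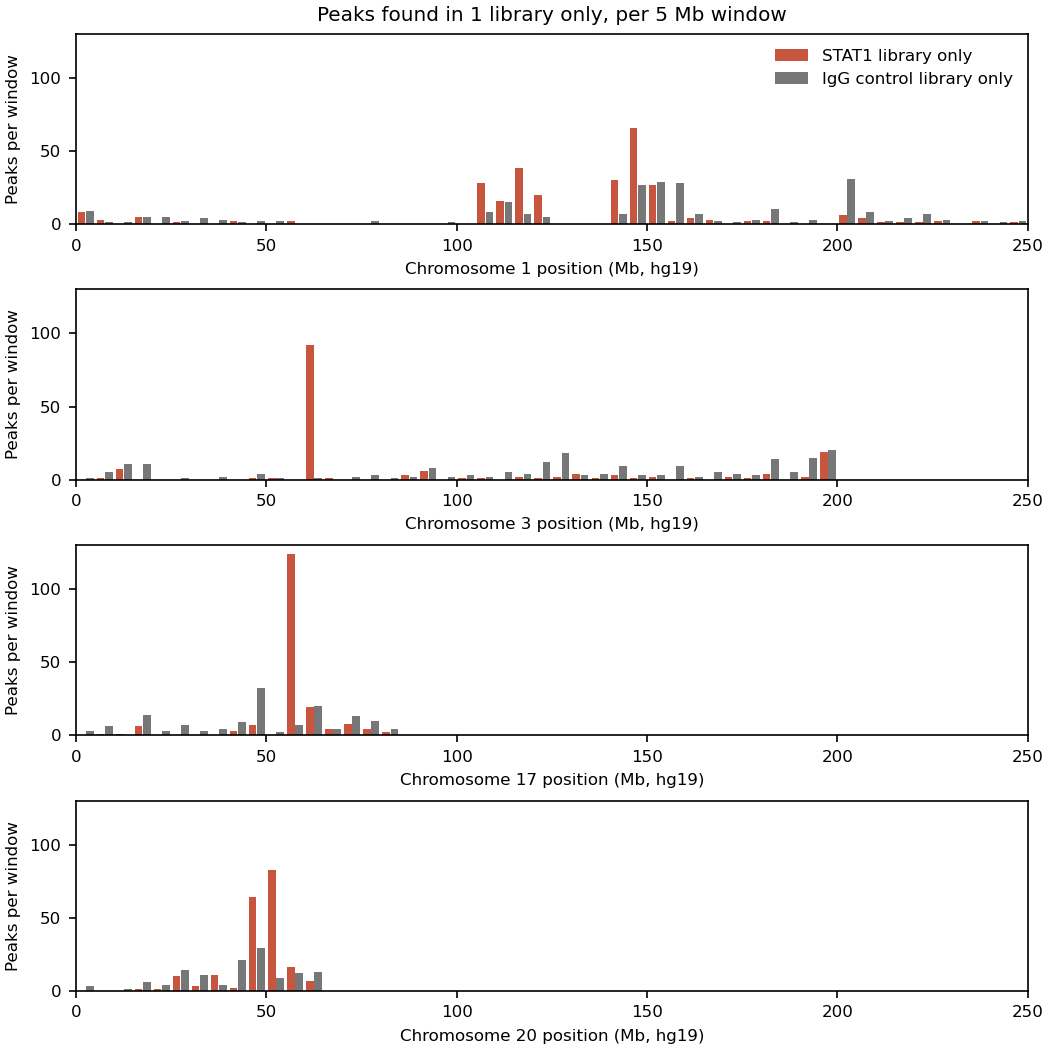
Number of peaks found in 1 library only (y axis) per 5 Mb window along chromosomes 1, 3, 17 and 20 (x axis, Mb in hg19). Bars are the STAT1 library (red) and the IgG control library (grey). STAT1-only peaks reach 124 in the chromosome 17 window from 55 to 60 Mb and 92 in the chromosome 3 window from 60 to 65 Mb, where there are 7 and 1 control-only peaks.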

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

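The tests in this part were chosen after the header values were seen. The STAT1 library held 3.71 tags per distinct tag position by its header, against 1.15 in the control library, a value outside the peak comparisons that was 3.23 times higher than in the control. Tall regions that collect most tags are argued against, because peaks held 1.09% of the STAT1 library's tags. Duplication of a library with few distinct fragments may account for it: the median in STAT1-only peaks was 3.63 tags per unit of score (the position-limited tag number), close to the library-wide 3.71, as an excess spread over the whole library would give. No biological explanation was tested, since the design has no second library of either kind. The 4372000 distinct tags, against 33258000 in the control library, set an expected 0.330 tags per peak width and the threshold of 7, so weak STAT1 peaks rest on few tags.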

How the results depend on the processing

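Of 37 alternatives over 8 results, 12 stayed within their bounds (1.5 times for a number of peaks, the 95% interval otherwise; for random placement, 1 SD). Of the alternatives, 15 were chosen after the data were seen. The number of peaks depended on the threshold. At or above the median score it was 1803 in the STAT1 list and 2158 in the control list, at 1.5 times the tag threshold 853 and 1572, and at 1.5 times the local fold 2050 and 1613, which turned the order of the libraries. That turn follows at least in part from depth and threshold, as control peaks at their threshold stand lower over the average background. The shared percentage of the STAT1 list was 31.2% where 50% of both peaks had to overlap, 43.0% with centres within 1000 bp, 43.4% at or above the median score and 41.0% at or above the median height. It was 70.1% at the control tag threshold and 30.7% without tall-peak windows. The shared percentage of the control list was, in that order, 21.1%, 28.9%, 36.3%, 26.5%, 9.78% and 19.9%, and 33.7% with lists of equal length. The 9.78% follows from the shorter STAT1 list, and for the other shifts the cause was not tested. The median height ratio of shared peaks was 1.16 by fold over local background, 1.19 without tall-peak windows and 2.30 by score per distinct tag. The ratio of shares on chromosomes 17 and 20 was 2.97 with STAT1 peaks at the control threshold. Crowded windows held 52.5% of STAT1-only peaks with 2 Mb windows, 32.7% with 10 Mb windows (the minimum scaled to the window) and 42.1% without tall-peak windows. Comparisons by start site, gene list, motif and annotation class, and their alternatives, were not run, since they need hg19 sequence or annotation. No paired analysis was possible because each group has 1 library. The depth of 4372000 distinct tags limits the STAT1 list: a STAT1 peak missing at a control-only site may lie below detection, as 3.26% of the weakest and 87.6% of the strongest control peaks were shared.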

Other observations

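In this part, the bounds for sharp peaks, tall-peak windows and crowded windows were chosen after the data were seen, as were the tests of the backgrounds at shared peaks, by window and near STAT1-only peaks, and the threshold test outside tall-peak windows. Some STAT1-only peaks were sharp: 16 stood at least 50-fold over their surroundings in the STAT1 library, 10 of them in tall-peak windows, where 7 of the 10 were tall themselves. The sharpest, in a tall-peak window on chromosome 22 at 16861584 to 16861734, had a 196.16-fold excess, a height of 248.7 and a score of 44. Of the 6 outside such windows, the 3 sharpest lay on chromosome 11 at 48867733 to 48867883 (89.07-fold, score 25) and at 48894725 to 48894875 (61.34-fold, score 31), and on chromosome 16 at 33896542 to 33896692 (55.8-fold, score 32). Their 5 Mb windows were not free of control signal. The chromosome 11 window held 30 control peaks, 15 of them shared, and the chromosome 16 window 40, with 19 shared. A shared peak lay close to each of the 3, at 48861851 to 48862001, at 48893006 to 48893156 and at 33887605 to 33887755 in turn. No repeat annotation was used, so it stayed open whether these sharp peaks lie in repeat sequence.

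A biologist would want to look again at the crowded windows on chromosomes 1, 3, 8, 16, 17 and 20, where STAT1-only peaks gather without tall peaks, 1 hypothesis being that the cells carry more copies of these regions, which would raise the background of both libraries. The control library's local background at its own peaks there was 1.52 times that in other windows (95% interval from resampled windows 1.35 to 1.83, and 1.501 to 1.562 with any 1 window left out), and 1.44 times (1.21 to 1.70) within 100 kb of STAT1-only peaks. The medians in other windows, 0.869 in the control library and 1.11 in the STAT1 library, lay near the floor of these backgrounds. Ratios against them may be limited by it, to a different degree in each library. By window the control background ran from 1.11 times (chromosome 20, 50 to 55 Mb, with 4.95 times in the STAT1 library) to 5.61 times (chromosome 3, 60 to 65 Mb, with 3.42 times in the STAT1 library). The control values of these windows rest on 10 and 6 control peaks in turn, so their spread is uncertain. Over all STAT1 peaks the STAT1 library's background was 3.28 times (2.30 to 4.28). That value and the control value come from different places, each library's own peaks. At the 46 shared peaks, the same places in both, the rise was 1.91 times (1.45 to 3.33) in the control library and 1.67 times (1.32 to 3.07) in the STAT1 library. Of these 46, 19 lay on chromosome 16 from 30 to 35 Mb, a window with 21 STAT1-only peaks. The fullest windows, on chromosomes 17 (55 to 60 Mb), 3 (60 to 65 Mb) and 20 (50 to 55 Mb), held 2, 5 and 1. The shared peaks therefore say little about the fullest windows. The bound set beforehand for extra copies, a control background of at least 1.5 times, was met by the 1.52, although its interval reached below that bound. All 12 of these windows had a control background above the median of other windows. Whether extra copies are the whole cause stayed open, as the libraries could hardly be compared at the same places in the fullest windows. Whether the low tag threshold of the STAT1 library was the cause stayed open by the planned test. At the control threshold these windows held 0.891 times their share of all STAT1-only peaks (0.695 to 1.11). This interval reached below the bound set beforehand for arguing against the threshold. In the added test outside tall-peak windows the value was 1.45 times (53 of 87 against 627 of 1489, interval from resampled windows 0.833 to 1.80). That interval stayed above the bound, so only the added test argues against the threshold as the whole cause, outside tall-peak windows. STAT1 binding sites gathered there cannot be told apart from extra copies, as by the antibody labels there is no STAT1 pull-down without stimulation, and no replicate; the windows' peaks had 0.487 times the median fold over surroundings of other STAT1-only peaks, a measure that a raised background lowers by construction.

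The crowded windows with tall peaks, 3 in number, held 67 STAT1-only and 45 control-only peaks. Repeat sequence collapsed in the genome build is a candidate explanation. The control background there was 1.47 times that in windows without tall peaks, with an interval of 1.27 to 8.45, and so few windows keep it open. By window its median was 7.55 on chromosome 2 (90 to 95 Mb), 2.92 on chromosome 1 (120 to 125 Mb) and 1.12 on chromosome 5 (175 to 180 Mb). In windows without tall peaks it was 0.886. The chromosome 5 window held 38 of the 69 control peaks and so weighs most on the pooled value.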
